A study of Mus musculus with 4 samples.

How the data were processed

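Poly(A) RNA from mouse embryonic stem cells was sequenced as 4 libraries, 2 of Drosha knockout cells and 2 of wild-type E14 cells, with a reverse-stranded TruSeq protocol on total RNA taken up in Trizol, per the labels. The deposited values were raw read counts per Ensembl gene, with 43629 gene identifiers in each library and no normalisation by the authors. Alignment used STAR 2.4.2a and counting featureCounts 1.4.5-p1 on build mm10, per the submitters' processing notes. The annotation release and the counting options for overlapping genes and reads with several matches were not given in the sources used here. Such options decide how reads are shared between a microRNA gene and its host, or between a gene and its pseudogenes, so those values are uncertain. Every count column belonged to a sample of the series, and every counted line carried an Ensembl gene identifier.

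Library groups came from the genotype and title labels. Names were taken from a gene name table, which gave a symbol for 42462 identifiers (97.3%). Coordinates, biotypes, transcript GC content and exon length came from the GENCODE M21 annotation of the same build, which may differ from the one used for counting. Library totals ran from 29264632 to 42322129 counts, so that 1 count was worth 0.0236 to 0.0342 CPM before TMM scaling. Counting error alone therefore limits genes below about 1 CPM, and a library without a count allows up to 3 counts. Counts were not collapsed by molecular identifiers, so such limits cover counting error only.

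Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter with the groups (minimum count 10, minimum total 15), a quasi-likelihood fit of group alone and Benjamini-Hochberg adjustment, with a threshold of 0.05. Log2 fold changes are knockout over wild type with a standard error. CPM values are TMM-scaled. The scaling factors were 1.055, 1.049, 0.995 and 0.908 for KO1, KO2, WT1 and WT2, and the median log2 fold change over all genes moved from -0.02 to 0.13 with library totals alone. Each knockout library was also fitted by itself against the wild types, where the lone library is assumed to vary like the wild-type pair. KO1 against KO2, and WT2 against WT1, were compared as log2 ratios of CPM with a prior count of 2 and without a test. Concordance of the alleles was set beside 20 simulations of unchanged libraries against the same controls.

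Gene lists, 27 in number, were fixed with their members before the data were examined. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists, and again with the correlation estimated for each list. None of the 9 called lists passed with an estimated correlation, where their adjusted p ran from 0.592 to 0.721. With 4 libraries that version has so few residual degrees of freedom that hardly any list could pass. It therefore cannot decide whether a list call depends on the correlation. Estimates for the ribosomal (-0.00474), neurectoderm (-0.0274) and glycolysis (-0.0343) lists were below the preset value. Those for the endoderm (0.535), fibroblast (0.423), formative epiblast (0.103), mitochondrial (0.0694), histone (0.0451) and microRNA host (0.0252) lists were above it. If these estimates hold, the preset test is too lenient for the lists above it, most of all endoderm and fibroblasts. The self-contained test fry called 5 lists. Named genes followed a rule fixed before the data were examined. It took 8 genes whatever their values, the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean log2 CPM of at least 1, and up to 2 raised and 2 lowered members of each list past the threshold, or else the member with the smallest p. Of the genes this rule took, 1 is not reported here. For comparisons of 1 library with 1 library it took the 5 largest ratios in each direction with at least 10 CPM in either library. Col4a1, Fn1, Mir22hg, H19, Rian, Meg3, Mir17hg, the microRNA genes and the Y-linked genes other than Eif2s3y were named after their values were seen.

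Libraries of each pair were compared by a chi-square over genes with at least 50 counts in the pair. GC and length trends were estimated after the data were seen, as smooth lowess curves of each library's log2 CPM against the mean of the libraries, and removed as offsets. For 3' UTR matches, the 7-base seed match of several microRNA families was compared with 15678 other 7-base sequences. The share of 50-base stretches of each ribosomal protein transcript that occur in other annotated genes was computed from the transcript sequences. Permutation tests were two-sided with 100000 resamples, and these steps and the plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

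The count test was tested on simulated data drawn from the means and library sizes of the real libraries for KO vs WT. With equal spread in both groups and 16607 genes tested, 27% of 100 genes changed 2-fold and 89% of 100 genes changed 4-fold were recovered, with 4 false calls. With the measured spread of each group and 16647 genes tested, 0% and 0% were recovered with 0 false calls, so a group pair as unequal as this one can leave real changes below the threshold. In that simulation 1308 unchanged genes had an unadjusted p under 0.05, against 770 with equal spread. Unadjusted p-values were therefore too small more often with unequal spread. In each simulation camera called the list of genes raised 2-fold and 0 of 20 random lists. Simulated genes were drawn independently, while in the data the estimated correlation within the endoderm list was 0.535. These list results therefore do not measure false list calls in the real libraries.

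Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, DESeq2 1.42.0, limma-voom, 2 other expression filters, a test against a 1.5-fold change, the replicate number as a block, leaving out each library in turn, other prior counts and separate controls. Alternatives added after the data were seen were the knockout libraries summed as 1 sample, GC and length trends removed, and genes of chromosomes 1, 15 and Y left out. Exon-level reads over the deleted parts of Drosha and small RNA levels were not analysed here.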

Results

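Gene expression was measured by poly(A) RNA sequencing in mouse embryonic stem cells of 129/Ola background grown in serum plus LIF. The samples were 2 libraries of Drosha knockout cells and 2 libraries of wild-type cells. DROSHA is the nuclear RNase that cuts primary microRNA transcripts, and the series asks how the transcriptome of cells without it differs from wild type. Knockout library 1 (KO1) carries a deletion of the proline-rich region of Drosha and knockout library 2 (KO2) a deletion of the region rich in arginine and serine, both labelled passage 7. Both wild-type libraries come from E14, a widely used embryonic stem cell line, labelled passage 33 (WT1) and passage 42 (WT2), and their labels call them re-used. The knockout titles also carry the mark d5, whose meaning the labels do not give. Genotype, passage, the origin of the libraries and whatever this mark stands for therefore coincide and cannot be told apart. The deposited counts summed to 29264632 in KO1, 42322129 in KO2, 40139219 in WT1 and 39657578 in WT2. A single count was worth 0.0342, 0.0236, 0.0249 and 0.0252 CPM (counts scaled to an equal library total) before TMM scaling, in that order. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

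Drosha itself (ENSMUSG00000022191, chromosome 15, 12824815 to 12935291, build mm10) was the first gene examined, since it checks the labels. Its normalised read count was 158 CPM in KO1 and 158 CPM in KO2, against 364 CPM in WT1 and 357 CPM in WT2. The knockout mean of 158 ± 0.427 CPM (SD, n = 2) lay below the wild-type mean of 360 ± 5.12 CPM (SD, n = 2), a fall on the log2 scale of -1.19 ± 0.11 (SE) for KO over WT. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes gave an adjusted p of 0.0482. Dgcr8 (ENSMUSG00000022718, chromosome 16, 18253948 to 18289246), which encodes the RNA-binding partner of DROSHA, rose from 107 ± 9.79 to 230 ± 4.09 CPM (SD, n = 2 each), a log2 fold change of 1.098 ± 0.13 with the same adjusted p. Dicer1, which encodes the cytoplasmic nuclease of the pathway, had a log2 fold change of -0.45 ± 0.11 and did not pass (edgeR adjusted p = 0.0742, and -0.07 ± 0.09 with GC and length trends removed). Gene-level counts do not show which part of Drosha was deleted, so they do not check the alleles, and chromosome 15 differed between the wild-type libraries as described below.

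**Figure D1:**
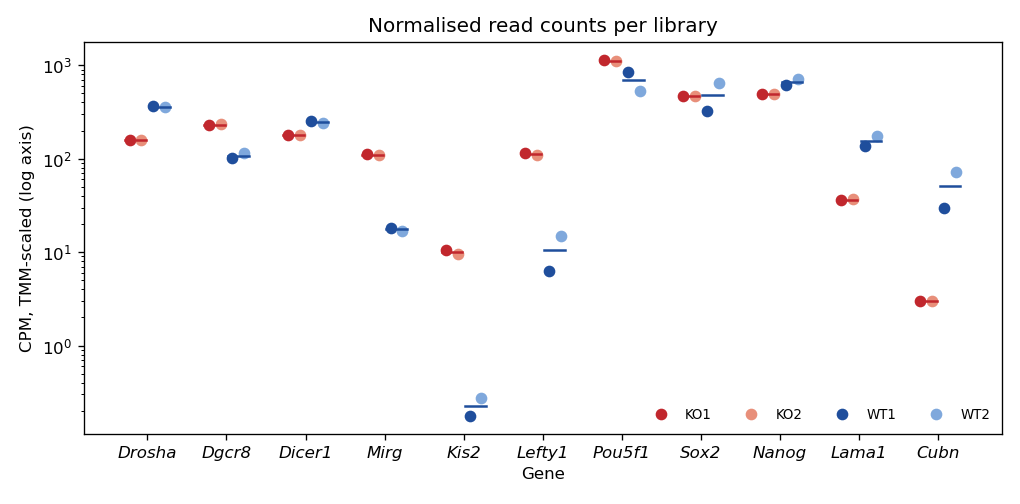
Normalised read counts (CPM, TMM-scaled, log axis) of 11 genes, with 1 point per library (KO1 and KO2 in reds, WT1 and WT2 in blues) and a line at each group mean of 2 libraries. Drosha lay at 158 CPM in each knockout library and at 357 to 364 CPM in the wild-type libraries, while Mirg lay at 109 to 112 CPM against 16.9 to 18.3 CPM.

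The largest rises in knockout over wild-type cells included Kis2, a non-coding RNA of chromosome X, with a log2 fold change of 5.46 ± 0.33 (10.04 ± 0.785 against 0.227 ± 0.0724 CPM, SD, n = 2 each). Lefty1, an inhibitor of NODAL signalling, rose from 10.6 ± 6.12 to 111 ± 3.52 CPM, a log2 fold change of 3.39 ± 0.47. Other genes with large rises were Pcsk1n (4.25 ± 0.38), Adgrg5 (3.98 ± 0.30), Trim67 (3.67 ± 0.38), the germ cell gene Nanos3 (3.42 ± 0.33) and Tulp1 (3.17 ± 0.28). The ribosomal pseudogenes Rpl36-ps2 (3.58 ± 0.56) and Rpl36-ps12 (3.52 ± 0.52) rose as well, but they can share reads with their parent gene and are uncertain. The largest falls were those of Cubn, an endocytic receptor of endoderm, at -4.10 ± 0.52, and of the germline gene Tex15 at -2.67 ± 0.34. Mageb16 (-2.21 ± 0.27), Fam208b (-2.19 ± 0.19), the laminin gene Lama1 (-2.09 ± 0.17), the zinc finger genes Zfp971 (-2.08 ± 0.28) and Zfp991 (-2.01 ± 0.31), Usp29 (-1.99 ± 0.31), Stk31 (-1.97 ± 0.21) and the pseudogene Rpl5-ps2 (-1.95 ± 0.24) followed. Adjusted p-values of these genes (edgeR quasi-likelihood test, Benjamini-Hochberg) lay between 0.0482 and 0.0499.

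Of 17022 genes tested, 597 rose and 330 fell in the knockouts at an adjusted p under 0.05, 927 in all, and 516 of the rises and 186 of the falls exceeded 2-fold. Protein-coding genes made up 525 of the rises and 280 of the falls. The smallest adjusted p was 0.0482, so every call lay close to the threshold, and 6320 genes had an unadjusted p under 0.05, where simulated data gave 770 or 1308 unchanged genes. No gene passed with the knockout libraries summed and counted as 1 sample, with the GC and length trends of the libraries removed, with upper-quartile scaling or with library totals alone, where 1821, 4309, 6267 and 6116 genes had an unadjusted p under 0.05 in edgeR. DESeq2 called 3757 genes, 2051 of them higher. Leaving out KO1 or KO2 gave 0 calls (1689 and 1944 genes at an unadjusted p under 0.05), and leaving out WT1 or WT2, where the spread comes from the knockout pair, gave 13572 and 11963.

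Transcripts that carry microRNAs were higher as a list, with members that went either way. The list of microRNA host transcripts also held microRNA genes, of which Mir290a and Mir3091 were measured, so it overlaps the microRNA genes described below. Of its 19 measured members, 15 had a fitted change above 0, and 3 rose and 0 fell past the threshold. Adjusted over the list alone, 10 members rose and 1 fell. Their median log2 fold change was 0.80 (camera, adjusted p = 0.0082, with 0.604 at an estimated correlation and 0.0543 in fry), and it was 1.42 with GC and length trends removed. Mirg (ENSMUSG00000097391, chromosome 12, 109729764 to 109749460), an imprinted non-coding RNA with 13 annotated microRNAs inside it, rose from 17.6 ± 0.953 to 111 ± 1.64 CPM (SD, n = 2 each), a log2 fold change of 2.65 ± 0.13. C130071C03Rik (chromosome 13, 83721381 to 83884194), which holds the microRNA gene Mir9-2, rose by 3.66 ± 0.49 on the log2 scale, from a wild-type mean of 0.0904 CPM. Both had an adjusted p of 0.0482 in edgeR. The third member past the threshold over all genes was Mir22hg, at 11.6 and 12.8 CPM in the knockouts and 3.73 and 4.69 CPM in the wild types. The imprinted RNA H19 was the member that fell with adjustment over the list alone, at 0.324 and 0.406 CPM against 2.76 and 1.28 CPM.

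Annotated microRNA genes, whose counts in poly(A) RNA come from longer transcripts over those loci, had a median log2 fold change of 2.47 over 71 measured genes, or 2.38 with the 11 genes absent from both wild-type libraries set to the value that 3 counts per library would give. Among them 21 rose and 0 fell, but most of the 21 lay in a few clusters, on chromosomes 12, X, 7 and 2. They are therefore not separate loci, and Mir541, Mir369, Mir496a and Mir412 lie inside Mirg, described above. Many were near the floor in the wild types, with Mir369, Mir298 and Mir106a at 0 CPM in both. Chosen after their values were seen, Mir293, Mir294 and Mir295 of the cluster most abundant in mouse embryonic stem cells (chromosome 7, 3220343 to 3220841) rose by 2.38 ± 0.29, 2.03 ± 0.21 and 2.42 ± 0.19 on the log2 scale. The cluster's Mir290a, Mir292, Mir291a and Mir291b did not pass (edgeR adjusted p = 0.0579, 0.0600, 0.0655 and 0.123), and they differed between the wild types, with Mir291b at 5.54 CPM in WT1 and 0.639 CPM in WT2. Mir18b (chromosome X, 52742331 to 52742413) had 2.85 and 2.39 CPM in KO1 and KO2 and a single count in each wild-type library, so no fold is given, and Mir106a next to it ends at 52742567, inside the span of Kis2 (ENSMUSG00000086173, chromosome X, 52742563 to 52744960, same strand). Mir293, Mir294, Mir295 and Mir18b had an adjusted p of 0.0482 in edgeR. A read over a microRNA gene inside another annotated gene can be assigned to either, or to neither, depending on counting options not given in the sources used here.

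Genes of the microRNA pathway and known microRNA targets did not move one way. Of the 20 genes of the microRNA machinery, Dgcr8 rose, Drosha fell and 18 did not pass, and the list did not pass in camera (adjusted p = 0.298) but passed downward in fry (adjusted p = 0.0120). Among 15 measured targets of the miR-290 and miR-302 families, which are the main microRNAs of embryonic stem cells, Lefty1 rose and 14 did not pass, and adjusted over the list alone 2 rose and 1 fell. Their median was -0.28, their mean 0.04 and the test pointed down without passing (adjusted p = 0.824). The cell cycle inhibitor Cdkn1a, a target of these families, had a log2 fold change of 0.45 ± 0.15 (edgeR adjusted p = 0.117, and 0.06 ± 0.10 with GC and length trends removed) and the Hippo kinase gene Lats2 one of -0.37 ± 0.27 (adjusted p = 0.352). Of 20 let-7 family targets, Mycn rose by 1.14 ± 0.16 and Hmga2 fell by 1.46 ± 0.19 on the log2 scale (edgeR adjusted p = 0.0482 each, and 0.70 ± 0.10 and -1.08 ± 0.15 with GC and length trends removed), with 4 higher and 6 lower adjusted over the list alone and no call for the list (median -0.45, adjusted p = 0.191).

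Pluripotency genes were expressed in every library and most did not pass. Pou5f1, which encodes OCT4, had 1121 ± 16.1 CPM in the knockouts and 688 ± 226 CPM in the wild types (log2 fold change 0.71 ± 0.26, edgeR adjusted p = 0.135, turning to -0.13 ± 0.16 with GC and length trends removed). Nanog (-0.45 ± 0.14, adjusted p = 0.0990, and -0.13 ± 0.10 with these trends removed) and Sox2 (-0.05 ± 0.36, adjusted p = 0.926) did not pass either, and Sox2 ranged from 320 CPM in WT1 to 649 CPM in WT2. Among 20 naive pluripotency genes Klf2 rose by 1.41 ± 0.14 and Klf5 fell by 0.98 ± 0.12 on the log2 scale, and adjusted over the list alone 2 rose and 2 fell. The list had a median of 0.03, a mean of -0.0043 and a test that pointed down (adjusted p = 0.835). Among 15 general pluripotency genes Utf1 (2.11 ± 0.31) and Tcf3 (1.58 ± 0.18) rose, with 2 higher and 2 lower adjusted over the list alone. That list had a median of -0.05, a mean of 0.19 and a test that pointed up (adjusted p = 0.887). With GC and length trends removed Klf2 was at 0.02, Tcf3 at 0.32 and Utf1 at 0.61. Tcf3 here is the gene ENSMUSG00000020167 of chromosome 10, matched by symbol, and not Tcf7l1, a separate member of the WNT signalling list. Its place among general pluripotency genes is therefore uncertain.

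Markers of formative and primed epiblast, the stage after naive pluripotency, were higher in the knockouts as a list (19 measured, median 0.59, camera adjusted p = 0.0082, and adjusted p = 0.719 with an estimated correlation). Zic2 rose by 2.51 ± 0.15 and Zic5 by 1.13 ± 0.13 on the log2 scale (edgeR adjusted p = 0.0482 each), 17 members did not pass, and 3 rose adjusted over the list alone. With GC and length trends removed Zic2 was at 1.34 ± 0.20 and Zic5 at 1.23 ± 0.11, and the list's median was 0.01 (camera adjusted p = 0.243). The list's median log2 ratio was -0.68 for WT2 over WT1. Without WT2 the list's adjusted p was 0.101.

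Endoderm markers were lower as a list, with 3 of 18 measured members lower, 0 higher and 10 lower adjusted over the list alone. The median log2 fold change was -1.89 (camera, adjusted p = 0.000539, and adjusted p = 0.719 with an estimated correlation), and it was -2.49 with GC and length trends removed. Lama1 and the type IV collagen gene Col4a1, both of basement membrane, and Cubn were the members that fell, Lama1 from 155 ± 26.6 to 36.4 ± 0.391 CPM and Cubn from 51.0 ± 29.8 to 2.98 ± 0.00482 CPM (SD, n = 2 each). The same list separated the wild-type libraries, with a median log2 ratio of 1.31 for WT2 over WT1. Cubn had 29.9 CPM in WT1 and 72.1 CPM in WT2.

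Neurectoderm and neuronal markers were higher as a list (12 measured, 2 higher, 0 lower, 3 higher adjusted over the list alone, median 0.87). The camera test gave an adjusted p of 0.0082, and an adjusted p of 0.592 with an estimated correlation. Pax6, a transcription factor of eye and neural tube, rose from 0.316 ± 0.0142 to 1.76 ± 0.248 CPM (SD, n = 2 each) and Tubb3, a neuronal tubulin, by 1.13 ± 0.14 on the log2 scale (edgeR adjusted p = 0.0482 each). With GC and length trends removed the median was 0.76, Pax6 was at 2.67 and Tubb3 at 0.19.

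Markers of fibroblasts and feeder cells were higher as a list with 0 of 16 members past the threshold over all genes or over the list alone (median 1.07, camera adjusted p = 0.0062, and adjusted p = 0.721 with an estimated correlation). The median was 0.63 over WT1 and 1.94 over WT2. Their share of all counts was 0.177% in KO1, 0.174% in KO2, 0.113% in WT1 and 0.163% in WT2. Most of this share was Fn1, at 1447, 1438, 963 and 1674 CPM in that order. Fn1 did not pass (log2 fold change 0.13 ± 0.30, edgeR adjusted p = 0.770), so the share does not measure feeder content. Dcn, the member with the smallest p, had 1.65 CPM in KO1, 0.541 CPM in KO2 and no count in either wild-type library (edgeR adjusted p = 0.0639). With GC and length trends removed the list's median was 0.45 (adjusted p = 0.0962), and without WT2 its adjusted p was 0.101. Among 13 trophoblast markers Tfap2c rose by 1.08 ± 0.13 on the log2 scale (edgeR adjusted p = 0.0482), 12 did not pass and 1 rose adjusted over the list alone, with no call for the list (adjusted p = 0.191, and 0.0207 without WT1). None of 10 markers of primitive streak and mesoderm passed (list adjusted p = 0.403), and Fgf8, with the smallest p, had 0.292 against 0.0779 CPM.

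**Figure D2:**
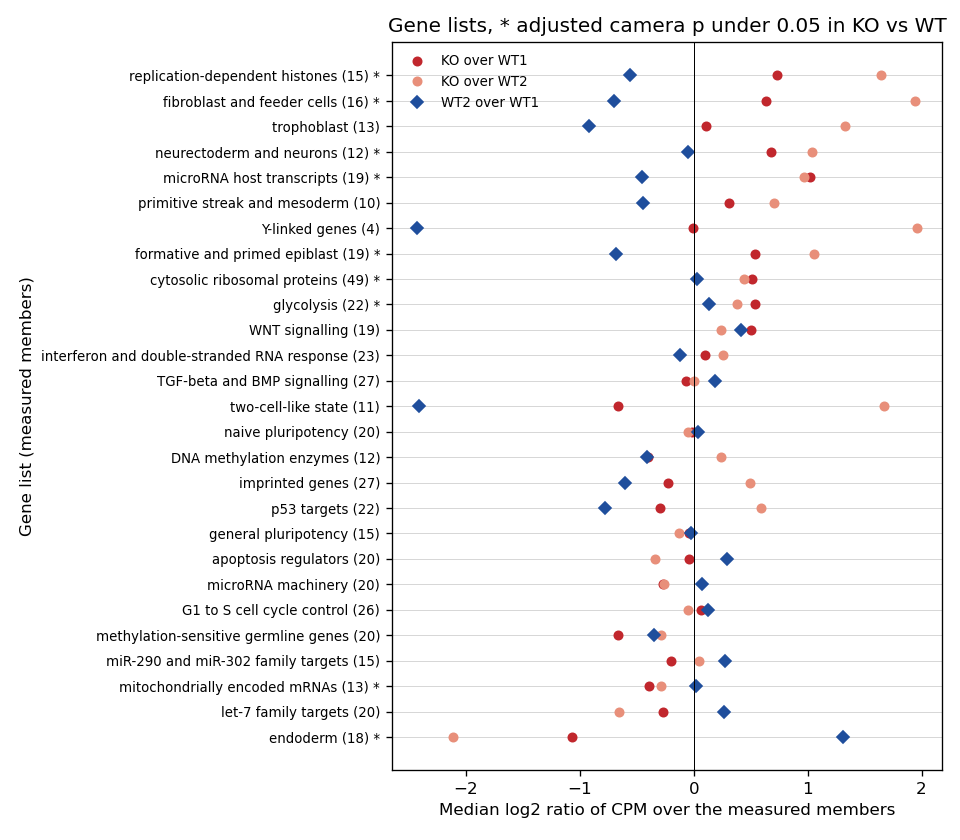
Median log2 ratio of CPM over the measured members of each of 27 gene lists, with circles for the mean of the knockout libraries over WT1 and over WT2 and diamonds for WT2 over WT1. An asterisk marks the 9 lists with an adjusted camera p under 0.05, and the endoderm list had the lowest median, at -1.89 in the fitted comparison.

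Cytosolic ribosomal protein mRNAs were higher as a list, with 6 of 49 higher, 0 lower and 23 higher adjusted over the list alone. The median log2 fold change was 0.48 (camera, adjusted p = 0.0024, and adjusted p = 0.592 with an estimated correlation), and 0.34 with GC and length trends removed. Without WT1 its adjusted p was 0.0641. They took 2.86% and 2.90% of the counts of KO1 and KO2, against 1.81% and 1.74% in WT1 and WT2. Rps16 rose by 2.44 ± 0.19 and Rplp2 by 1.48 ± 0.13 on the log2 scale (edgeR adjusted p = 0.0482 each), and since many of these genes have processed pseudogenes, single members are uncertain. Glycolysis genes were higher as a list (22 measured, 2 higher, 0 lower, 5 higher adjusted over the list alone, median 0.45, adjusted p = 0.0082, and adjusted p = 0.592 with an estimated correlation). The lactate transporter gene Slc16a3 rose by 1.30 ± 0.15 and the aldolase gene Aldoa by 1.07 ± 0.12 (edgeR adjusted p = 0.0482 each), and with trends removed they were at 0.61 ± 0.10 and 0.31 ± 0.11 and the list's median was 0.25 (adjusted p = 0.0962), with an adjusted p of 0.0525 without WT1. Mitochondrially encoded mRNAs were lower as a list (13 measured, median -0.37, adjusted p = 0.0261, and adjusted p = 0.719 with an estimated correlation), with mt-Atp8 lower by itself at -1.42 ± 0.21 (-0.73 ± 0.26 with trends removed) and 1 higher and 2 lower adjusted over the list alone. Genes of the mitochondrial chromosome took 2.87% and 2.96% of the counts of KO1 and KO2, against 3.48% and 2.93% in WT1 and WT2, so the groups overlapped. The list's median turned to 0.21 with trends removed, and its adjusted p was 0.0988 without KO1 and 0.0777 without WT1. Replication-dependent histone mRNAs, which mostly lack poly(A) tails, were higher as a list (15 measured, 2 higher, 0 lower, 5 higher and 1 lower adjusted over the list alone, median 1.21). The camera test gave an adjusted p of 0.0022, and an adjusted p of 0.592 with an estimated correlation, and the median was 0.67 with trends removed. Among members with at least 1 CPM in at least 2 libraries the adjusted p was 0.226. They took 0.007% of the counts in each knockout library and 0.008% in each wild-type library, and Hist1h3c (3.03 ± 0.41) and Hist1h4d (2.98 ± 0.44) rose at 0.997 and 0.755 CPM.

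The remaining lists did not pass in camera. In the interferon and double-stranded RNA response list Ifit1, an antiviral gene, rose from 0.0528 ± 0.00385 to 0.631 ± 0.159 CPM (SD, n = 2 each, edgeR adjusted p = 0.0482), 22 of 23 did not pass, and 5 rose and 2 fell adjusted over the list alone (list adjusted p = 0.725). Among 27 imprinted genes Mirg and Nespas (2.28 ± 0.30, edgeR adjusted p = 0.0482) rose and 7 rose and 3 fell adjusted over the list alone. The imprinted list had a median of -0.03, a mean of 0.15 and an upward test (adjusted p = 0.582). Of 27 genes of TGF-beta and BMP signalling, Lefty1 and the inhibitory SMAD gene Smad6 (2.06 ± 0.26) rose, with 2 higher and 1 lower adjusted over the list alone. The list had a median of 0.05, a mean of 0.18 and a downward test (camera adjusted p = 0.824). With GC and length trends removed Smad6 was at 0.82 ± 0.22 and Lefty1 at 2.29 ± 0.57. The caspase inhibitor gene Xiap (-0.92 ± 0.12) was the 1 member that fell among 20 apoptosis regulators (list adjusted p = 0.605), at -0.24 ± 0.14 with GC and length trends removed, and Stk31 the 1 that fell among 20 methylation-sensitive germline genes (list adjusted p = 0.179, and 0.0159 without WT2), with the same counts over each list alone.

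No member passed among 22 p53 targets (adjusted p = 0.830, median -0.03, mean 0.05), 26 genes of G1 to S control (adjusted p = 0.824, with 4 higher and 4 lower adjusted over the list alone), 12 DNA methylation enzymes (adjusted p = 0.568, with 1 higher and 1 lower adjusted over the list alone), 19 WNT signalling genes (adjusted p = 0.520), 11 two-cell-like genes (adjusted p = 0.582) or 4 Y-linked genes (adjusted p = 0.545). Their members with the smallest p were Bax (1.31 ± 0.30, edgeR adjusted p = 0.0671), E2f1 (0.84 ± 0.14, adjusted p = 0.0502), Dnmt3a (0.66 ± 0.13, adjusted p = 0.0586), Apc (-0.80 ± 0.14, adjusted p = 0.0539), Pramel7 (-1.68 ± 1.13, adjusted p = 0.329) and Eif2s3y (1.06 ± 0.54, adjusted p = 0.224). Bax turned to -0.19 ± 0.11 and E2f1 to -0.14 ± 0.24 with GC and length trends removed, and Apc was at -0.28 ± 0.11. The median for WT2 over WT1 was -0.78 for the p53 targets, -2.41 for the two-cell-like genes and -2.43 for the Y-linked genes. Without WT1 these lists passed upward at an adjusted p of 0.0407, 0.0158 and 0.0347, and without WT2 the DNA methylation enzymes passed downward at 0.0347.

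Expression ratios between knockout and wild-type libraries followed the GC content of the transcripts. Across 12533 genes, which are not independent replicates, the Spearman correlation of the log2 ratio with GC content was 0.717 for KO over WT, 0.621 for KO over WT1, 0.701 for KO over WT2, -0.416 for WT2 over WT1 and -0.377 for KO2 over KO1. The median log2 ratio for KO over WT was -0.57 in the fifth of genes with the lowest GC content (up to 43.8%) and 0.89 in the fifth with the highest (from 55.4%). For KO2 over KO1 the same medians were 0.04 and -0.05. Genes called higher had a median GC content of 57.2% and those called lower 42.7%, against 49.9% over all genes tested. With smooth GC and length trends removed, an alternative added after the data were seen, 879 of the 927 called genes had the same direction. The 20 genes with the largest changes all did, but they were picked for changes larger than this trend, so their kept direction is no check. Drosha (-1.30 ± 0.08), Dgcr8 (1.36 ± 0.09), Mirg (2.58 ± 0.09) and Kis2 (5.77 ± 0.27) ranked 7, 13, 1 and 2 by p among all genes. Some other called genes moved towards 0, with Lefty1 at 2.29 ± 0.57 (rank 2069), Zic2 at 1.34 ± 0.20, Smad6 at 0.82 ± 0.22, Aldoa at 0.31 ± 0.11 (rank 4127) and Xiap at -0.24 ± 0.14 (rank 7736).

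The knockout libraries, labelled with different deletions, had nearly the same transcriptome. Whether they came from separate cultures is not labelled, so this likeness cannot be credited to the deletions. Among 9591 genes with at least 10 CPM, 0 differed by more than 2-fold between KO1 and KO2, and the SD of the log2 ratio was 0.0761, against 0.602 and 768 genes (8.31%) for the wild-type libraries. The largest differences for KO2 over KO1 were in Lars2 (383 against 282 CPM), Zfp991, Zfp111, Zfp386 and C9orf72 on the higher side and Rps2-ps10 (11.6 against 18.4 CPM), Tpgs1, Gatc, Zfp628 and Junb on the lower side. With 1 library per allele these differences have no replicate check and no p-value. The biological coefficient of variation was 0.0226 between the knockout libraries and 0.372 between the wild-type libraries. The knockout libraries differed by more than sampling noise, with a chi-square per gene of 2.26 and 14.3% of 14837 genes at p under 0.05. They were kept as 2 samples as labelled, although separate preparations of one RNA would also exceed sampling noise, and with the libraries summed edgeR made 0 calls (1821 genes at an unadjusted p under 0.05, and 3757 calls by DESeq2 with the libraries kept apart). Each knockout library tested by itself against the wild types gave 0 calls in edgeR, with 1949 and 1716 genes at an unadjusted p under 0.05 for KO1 and KO2.

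The log2 fold changes of the alleles were correlated, in a comparison where they share controls. The correlation of their log2 fold changes across 12583 genes was 0.990, where simulated unchanged libraries against the same controls gave 0.966, and the covariance was 0.591 against a simulated 0.155. Against separate wild-type libraries the correlation was 0.694 (KO1 over WT1 and KO2 over WT2) or 0.689 (crossed), and simulated libraries gave a value near 0. Simulated libraries were drawn independently around the same means, so a value near 0 was built in. They held no GC trend and no difference between sets of libraries, so they cannot tell shared effects of the deletions from such differences. In 47 genes the alleles lay on opposite sides of both wild-type libraries.

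The wild-type libraries differed from each other in the genes of chromosomes 1, 15 and Y. Genes of chromosome 1 were higher in WT2 than in WT1, with a median ratio of 1.51-fold over 738 genes (log2 0.60), and genes of chromosome 15 lower, with a median of 0.65-fold over 486 genes (log2 -0.61). The Y-linked genes Ddx3y (102 CPM in WT1, 11.4 CPM in WT2), Eif2s3y (59.1 and 19.97 CPM) and Uty (33.3 and 10.1 CPM) were lower in WT2. With GC and length trends removed the medians were 0.53 for chromosome 1 and -0.53 for chromosome 15 for WT2 over WT1, while for KO over WT1 they were -0.02 and 0.06. Single genes differed more, and most of the extreme ones lay on other chromosomes. Highest in WT2 over WT1 were Stra8 (chromosome 6, 131 against 10.1 CPM), Cyp2b23 (chromosome 7), Tgfbi (chromosome 13), Miip (chromosome 4) and Msc (chromosome 1). Lowest were Plekhg1 (chromosome 10, 9.25 against 144 CPM), Usp26 (chromosome X), Dglucy (chromosome 12), Rgs9 (chromosome 11) and Wnt7b (chromosome 15). Calls for KO over WT on chromosome 1 were 15 higher and 24 lower of 1070 genes, and on chromosome 15 they were 21 higher and 3 lower of 666. Lefty1 lies on chromosome 1 (14.97 CPM in WT2, 6.31 CPM in WT1) and Drosha on chromosome 15. Without the genes of chromosomes 1, 15 and Y, an alternative added after the data were seen, 1832 genes were called. With 1 library per passage label no p-value can be given.

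**Figure D3:**
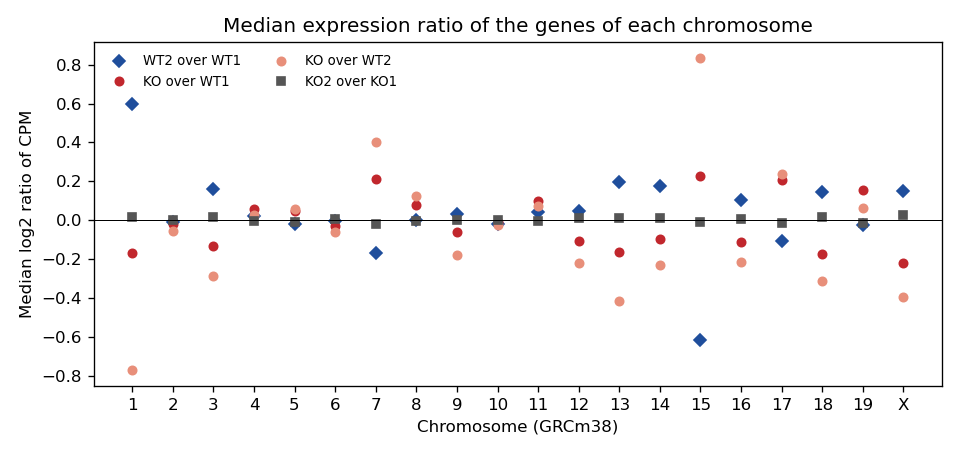
Median log2 ratio of CPM over the genes of each chromosome, with diamonds for WT2 over WT1, circles for the mean of the knockout libraries over WT1 and over WT2, and squares for KO2 over KO1. Chromosome 1 stood at 0.60 and chromosome 15 at -0.61 for WT2 over WT1.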

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

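Summing the knockout libraries, removing GC and length trends and leaving out chromosomes 1, 15 and Y were chosen after the results were seen, and the other alternatives before. The count of genes past the threshold for KO over WT, 927 with 597 higher and 330 lower, moved widely. Each called gene that was tested had the same direction under the alternatives to the KO over WT count, except that 879 of 927 did with GC and length trends removed. All 927 called genes had both knockout libraries above or both below both wild-type libraries. Leaving out a library could therefore hardly turn them, and for such alternatives the agreement is no check. DESeq2 size factors gave 1017 genes and limma-voom 1369 (907 higher). More genes were called with DESeq2 (3757, with 2051 higher and 1706 lower), with no expression filter (2663, with 1608 higher and 1055 lower), with a filter of 1 CPM (1440, with 596 lower) and without chromosomes 1, 15 and Y (1832, with 1065 higher and 767 lower). There were 0 calls, 0 higher and 0 lower, with upper-quartile factors, with library totals, against a 1.5-fold change, with the knockout libraries summed and with GC and length trends removed. In edgeR 6267, 6116, 3038, 1821 and 4309 genes then had an unadjusted p under 0.05. DESeq2 was not run under these settings, and its 3757 calls came from the separate libraries with its own size factors. The smallest adjusted p in edgeR was 0.0482 with TMM, 0.0520 with upper-quartile factors and 0.0542 with library totals. With other scaling, small shifts in adjusted p therefore ended every call. The shift was larger with GC and length trends removed (0.0894) and against a 1.5-fold change (0.112). Leaving out 1 library gave from 0 to 13572 calls, 0 to 6974 higher and 0 to 6598 lower. The high counts came without WT1 (13572) or WT2 (11963), where the spread is that of the knockout pair, and the counts of 0 without KO1 or KO2. Each knockout by itself gave 0 calls except without an expression filter, where 380 (KO1) and 314 (KO2) passed. The correlation between the alleles fell from 0.990 to 0.694 or 0.689 with separate controls.

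With the replicate number as a block, 1929 genes passed (1353 higher and 576 lower), and 8 lists. The same-numbered libraries share only a number in the labels, and the correlation of their deviations was 0.123 across genes. The replicate block moved Sox2 to 0.04 and ended the call of the mitochondrially encoded mRNAs (adjusted p = 0.0560).

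The number of lists past the threshold was 9, and 8 to 10 under other scaling, filters, summed knockouts and left-out libraries or chromosomes. It was 5 with GC and length trends removed, 5 with fry and 0 with an estimated correlation, a version that could hardly pass with 4 libraries. In fry microRNA machinery passed downward (adjusted p = 0.0120), and the lists of microRNA hosts (0.0543), formative epiblast (0.0681), mitochondrially encoded mRNAs (0.0681), endoderm (0.1497) and fibroblasts (0.153) did not pass. Lists not called for KO over WT changed direction as follows, and the cause was not tested. With trends removed the adjusted p was 0.9998 for microRNA machinery, 0.343 for general pluripotency, 0.343 for primitive streak, 0.9998 for TGF-beta signalling and 0.575 for WNT signalling. The mitochondrially encoded mRNAs, past the threshold before, turned upward at 0.343. In fry it was 0.816 for miR-290 and miR-302 targets, 0.624 for naive pluripotency, 0.941 for G1 to S control and 0.633 for TGF-beta signalling, and without chromosomes 1, 15 and Y it was 0.853 for naive pluripotency. Leaving out 1 wild-type library turned general pluripotency (0.804 to 0.932 over the left-out libraries), two-cell-like genes (0.0158 to 0.595), p53 targets (0.0407 to 0.894), G1 to S control (0.636 to 0.932), DNA methylation enzymes (0.0347 to 0.809), imprinted genes (0.264 to 0.791) and Y-linked genes (0.0347 to 0.932).

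Of the 60 genes named for KO over WT and run under the alternatives, 5 changed sign, none of them past the threshold. With trends removed Pou5f1 was at -0.13, Bax at -0.19 and E2f1 at -0.14. Sox2 was at 0.11 with library totals and 0.04 with limma-voom, and from -0.47 to 0.55 without 1 library, and Pramel7 from -2.55 to 0.81. The cause was not tested. Depth limited genes below about 1 CPM, such as Ifit1, Hist1h3c and Hist1h4d.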

Other observations

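The tests of the knockout pair and of the chromosomes were chosen after the results were seen, and those of the ribosomal proteins, seed matches and microRNA hosts before, apart from the p of the ribosomal list with trends removed. A count of windows on chromosome 15 with trends removed was added after the first count was seen.

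Genes that contain a microRNA were compared with other genes of the same coding status, and the coding classes were not tested against each other. Over 29 non-coding genes with an annotated microRNA on their strand the median log2 fold change for KO over WT was 0.80 (6 higher, 0 lower), against -0.10 over 955 other non-coding genes (two-sided permutation test over genes, p = 4e-05). Over 617 protein-coding hosts it was 0.19 and over 13618 other protein-coding genes 0.00 (permutation p = 2e-05). With GC and length trends removed these medians were 1.01, 0.03, 0.04 and 0.00. The permutation tests were run only before that removal. They treat genes as replicates, so their p-values do not measure the spread between libraries. The bounds set in advance, above 0.5 for non-coding hosts and within 0.2 of 0 for protein-coding hosts, were both met, the latter narrowly. One hypothesis is that non-coding hosts such as Mirg may build up as uncut primary transcripts when DROSHA is missing, and the rise of Dgcr8, whose mRNA is a known substrate of the same complex, would go with it. Against it, Rian, an abundant non-coding host named after its value was seen, had a log2 fold change of 0.07 ± 0.19. Meg3 and Mir17hg, also abundant, were higher by 0.80 ± 0.16 and 1.12 ± 0.33 without passing (edgeR adjusted p = 0.0569 and 0.0925). Of the 29 non-coding hosts, 16 had both knockouts above both wild types and 4 had both below. Genotype and library origin coincide, so no value here separates this from a difference between sets of libraries.

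Loss of repression by the main embryonic stem cell microRNAs was tested with matches to their seed in 3' UTRs. The 2073 of 11473 genes with the 7-base match AGCACTT were shifted by 0.04 ± 0.01 (SE) on the log2 scale over WT1 and by 0.04 ± 0.02 over WT2, after adjustment for other sequence properties. The match ranked 89 and 224 of 15678 sequences, and 9421 for WT2 over WT1. The bound set in advance, the first 1% of sequences against each wild-type library, was met over WT1 and missed over WT2, so the result could not decide. No match of the other families run lay in the first 1% over either wild type, and the overlapping miR-17 match GCACTTT ranked 172 over WT1 and 7100 over WT2, and that of let-7 13019 and 4547. The shift may reflect lost repression, but A- and T-rich sequences led the ranking over WT1 (TTTTTTT) and over WT2 (AAAAAAA).

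The knockout libraries were nearly alike although they carry different deletions. With trends removed the chi-square per gene was 1.7 (median 0.603, where sampling gives 0.455), above the bound of 1.5 set against a single library sequenced again, but a spread beyond sampling noise can also come from separate sequencing runs, so this stays open. Libraries from one RNA or one culture could also give the coefficient of variation of 0.0226, and so could close clones grown side by side, which cannot be told apart here. Any of these would make the spread within the knockouts too small, and the count of calls fell to 0 with the libraries summed. Biological likeness of the alleles remains open.

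Chromosomes 1 and 15 differed between the wild-type libraries. A GC or length bias as the whole source is argued against by the chromosome 1 median of 0.53 with trends removed. On chromosome 1, 100% of 10 windows of 20 Mb had a median above 0.3 for WT2 over WT1, and a gain of the whole chromosome in part or all of the WT2 cells is a candidate explanation. On chromosome 15, 50% of 6 windows lay below -0.3, which could not decide by the same rule, and the later count with trends removed gave 6 of 6. No DNA measurement was analysed here, and passage is an open biological difference between these libraries.

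Ribosomal protein mRNAs were higher in both knockout libraries. With GC and length trends removed the list's median was 0.34 (95% bootstrap interval over genes 0.20 to 0.41) against 0.48 before. That interval takes genes as replicates and does not measure the spread between libraries. The list still passed (camera adjusted p = 0.0073 at the preset correlation), which counts against these trends as the whole source. That call is fragile, since before removal the list did not pass without WT1. The camera version with an estimated correlation (adjusted p = 0.592 before removal) could hardly pass with 4 libraries and decides nothing. By the bounds set in advance (below 0.5 of the first median, or above 0.75 of it) the value decided nothing, and the reading from the list's p was adopted after it was seen. A part of the rise may come from these trends, and the fold change correlated with GC content (Spearman 0.368, permutation p = 0.0093, across 49 genes). Reads shared with pseudogenes remained open, since the correlation with the shared share was -0.265 (permutation p = 0.066) and members with less sharing had a median of 0.52 against 0.31 (permutation p = 0.58). A difference between knockout and wild-type cells and one between sets of libraries cannot be told apart.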
